A study of Mus musculus with 2 samples.

How the data were processed

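Mouse lung cell suspensions at embryonic day 12.5, 1 labelled CTRL and 1 labelled CKO, were profiled with the 10x Genomics Chromium 3′ kit (version 3), with 1 library per group. The labels speak of whole lung cells, of nuclei and of epithelial cells in different places. The cell classes found went beyond epithelium to mesenchyme, endothelium and blood. They also held cardiomyocyte-like cells and, in CKO, skeletal muscle-like cells. The deposited matrices hold counts: whole UMI counts per gene and barcode, made by Cell Ranger 7.1.0 per the file headers, with STAR and mm10 named in the submitters' processing notes. Seurat 4.4.0 is also named there, but the deposited values carry no normalization. The smallest barcode total was 500 UMIs in both files. The labels state that about 5000 cells were captured per library, whereas the files hold 8385 and 10217 barcodes. Gene positions came from GENCODE M21, in which 32158 of the 32285 gene identifiers were found.

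Cells with at least 1000 detected genes and at most 10% mitochondrial UMIs were kept (7113 in CTRL and 8735 in CKO). Scrublet in scanpy 1.11.5 scored doublets in each library. Its automatic threshold marked 2 and 1 barcodes, so barcodes with a score from 0.25 were marked instead, which removed 170 (2.39%) and 295 (3.38%). Both libraries were clustered together: counts were scaled to 10000 UMIs per cell and log-transformed, and 3000 variable genes, 40 principal components, 20 neighbours and Leiden clustering at resolution 1 (igraph 0.11.9) were used. Clusters were named from 18 fixed lists of cell type markers. A class needed 3 markers at 4 times the median cluster, a mean elevation of 1.3 on the log2 scale and marker genes among the 50 leading genes; a remaining cluster with mesenchymal markers was called mesenchymal-like at a Tbx4 plus Tbx5 level of 40 CPM or more and other mesenchymal-like below it. The doublet score, these naming thresholds, the split by Tbx4 and Tbx5 and the use of 1 endothelial cluster in place of the class, whose second cluster was almost only CKO, were set after the data had been examined. Ratios of marker genes used for naming were not reported, except those picked by the rule for named genes or held in a gene list, such as Myh11, since naming by a marker bears on its ratio.

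UMIs were summed over the cells of a class in each library and divided by the class total to give counts per 1e6 UMIs (CPM). Ratios were taken as CKO over CTRL after adding 0.5 UMIs, with exact conditional binomial intervals; levels had exact Poisson intervals and shares exact Clopper-Pearson intervals, all at 95%. No test between groups was run. Genes entered the counts by size of ratio at 20 CPM or more in at least 1 library and 100 UMIs or more over both. Before the data were examined, 24 gene lists were fixed; members at 5 CPM or more in a library entered a list's median, which was ranked among 10000 random lists matched on expression in 20 bins, and its interval came from 1000 draws of the counts. The beta protocadherin list had too few members above that level for a median. Shares of cells with a UMI were taken after thinning each cell to 5000 UMIs, with shallower cells left out.

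The rule for named genes was also fixed beforehand. It took the 12 largest and 12 smallest ratios in epithelial-like cells, 8 and 8 in mesenchymal-like cells, 5 and 5 in endothelial-like cells, and the 6 largest differences of the log2 ratio between epithelial-like and mesenchymal-like cells each way. It left out predicted, mitochondrial, ribosomal protein, haemoglobin and Y-linked genes, Xist and Tsix, but no other X-linked gene, and named from each list the 2 members with the largest ratio and the 2 of highest level. A few further list members (among them Sox2, Sox9, Shh, Etv5, Wnt7b, Cldn4, Igf2 and Cdkn1c) were named because of their place in lung development or imprinting. A gene that the rule picked is not reported here.

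The alternatives were TMM scaling (edgeR 4.0.16, R 4.3.3), other cell and gene filters (50 CPM, or no CPM minimum with 10 UMIs in place of 100), doublets kept, other clusterings, equal weight per cell, thinned cells, and a total without mitochondrial, ribosomal protein and haemoglobin genes. Another 3 were added after the data had been examined: without the low-UMI epithelial-like cluster, cells with an Nkx2-1 UMI only, and cells with a Tbx5 UMI only. The steps were tested on Poisson counts simulated from the pooled profile of both libraries, with true folds set for some genes: 44% of true 2-fold and 100% of true 4-fold differences in epithelial-like cells came out at 2-fold or more, and 0% of unaltered genes did. The simulated counts held no variation between cells, embryos, cell mixtures or libraries. They therefore do not measure how many unaltered genes reach 2-fold in the real libraries. Analyses used Python 3.11.15.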

Results

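The data were 2 single-cell RNA libraries of mouse lung at embryonic day 12.5, when the lung is branching. One library came from a control embryo lung (CTRL) and the other from a conditional knockout (CKO). The series title names CTCF, a DNA-binding protein that shapes chromatin loops together with cohesin; the genotype label names neither the deleted gene nor the Cre line. The CTRL library held 8385 barcodes and 136453096 unique molecular identifiers (UMIs), and the CKO library held 10217 barcodes and 160133243 UMIs. After filtering, 6943 CTRL cells (median 16073 UMIs) and 8440 CKO cells (median 14792.5 UMIs) were kept. With 1 library per group, no difference below has a replicate check, and all intervals are 95% intervals that cover counting error only. Although both libraries were labelled male, Xist, the RNA that coats the inactive X chromosome of females, stood at 592 counts per 1e6 UMIs (CPM) in CKO and 0.630 CPM in CTRL. The Y-linked genes Uty, Eif2s3y and Kdm5d had 0 UMIs in kept CKO cells and 11965, 5912 and 2742 UMIs in CTRL; Ddx3y, also Y-linked, had 312 in CKO and 7411 in CTRL. Sex therefore went with genotype in every comparison.

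The first question was which cells each suspension held. Lung mesenchyme was the main class, at 69.6% of CTRL cells (68.5 to 70.7, exact Clopper-Pearson) and 47.9% of CKO cells (46.8 to 49.0). Epithelial-like cells made up 7.50% of CTRL (6.90 to 8.15, 521 cells) and 4.86% of CKO (4.41 to 5.34, 410 cells). Mesenchymal cells with little Tbx4 and Tbx5, the T-box genes of lung mesenchyme, made up 19.8% of CKO (1667 cells) and 0.0144% of CTRL (1 cell). Skeletal muscle-like cells made up 1.49% of CKO (126 cells); CTRL had 0 of 6943 cells, which allows a share of up to 0.0432% as 3 cells of the total (0.0531% by Clopper-Pearson). Cardiomyocyte-like cells made up 1.28% of CTRL and 2.96% of CKO, but 0.0864% and 0.391% at Leiden resolution 0.5 and 0.0856% and 0.667% with no cell filter, where most of these cells were named otherwise. Cartilage-like cells made up 1.60% and 3.02%. In all, 6 clusters drew at least 90% of their cells from CKO and held 2270 CKO cells (26.9%) against 26 CTRL cells (0.374%). Without those clusters the epithelial share was 7.53% in CTRL and 6.65% in CKO, with intervals of 6.92 to 8.18 and 6.04 to 7.30, and the mesenchymal share was 69.9% and 65.5%. A cluster found in 1 library may reflect that library and not a cell type.

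**Figure D1:**
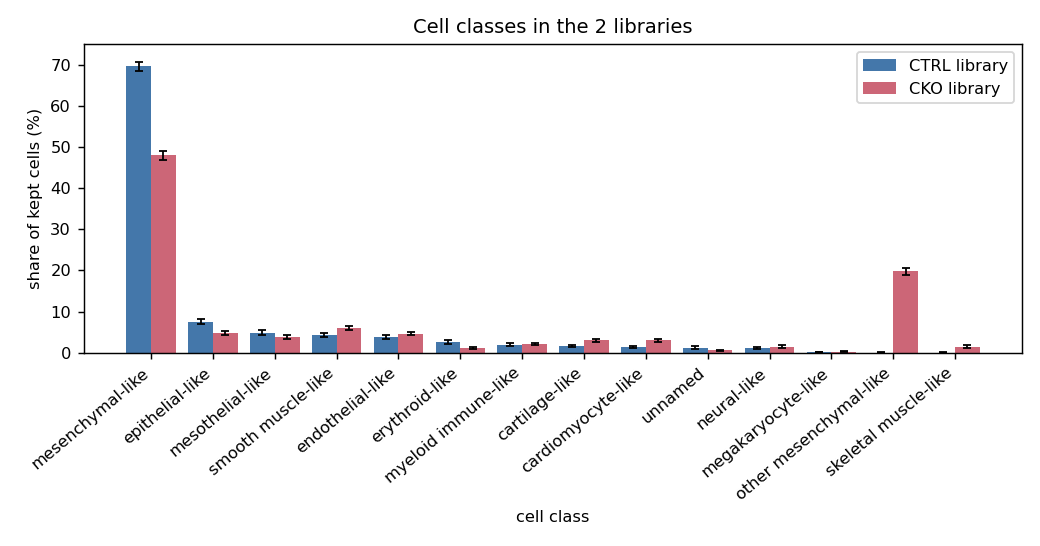
Share of kept cells (%, vertical axis) in each cell class for the CTRL and CKO libraries, with exact 95% Clopper-Pearson intervals as error bars. Other mesenchymal-like cells stand at 19.8% in CKO and 0.0144% in CTRL.

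The next question was how epithelial-like cells of the CKO lung differed from those of the control, beginning with Ctcf itself (ENSMUSG00000005698, chromosome 8, 105636568 to 105682922, plus strand, mm10). Ctcf stood at 223 CPM in CTRL (214 to 232) and 171 CPM in CKO (162 to 181), a log2 ratio of -0.38 (-0.48 to -0.28). The log2 ratio of Ctcf was -0.08 in mesenchymal-like cells, -0.19 in the compared endothelial cluster and -0.19 in mesothelial-like cells. The assay reads the 3′ end of transcripts and the labels do not give the deleted exons, so these values neither show nor exclude a deletion. Among 11 measured genes of the cohesin and CTCF list, 1 was over 1.5-fold higher, 0 were lower and 10 lay between, with a median log2 ratio of -0.08 (17.0th percentile of 10000 expression-matched random lists), which turned to 0.02 in thinned cells. Stag1, a cohesin subunit, stood at 262 CPM in CTRL and 471 CPM in CKO (log2 ratio 0.85); Pds5a, a cohesin regulator, had a log2 ratio of -0.53 and the core subunit Smc3 one of 0.03.

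Genes of the p53 response stood far higher in CKO epithelial-like cells. Of 25 measured p53 target genes, 23 were over 1.5-fold higher, 0 were lower and 2 lay between, with a median log2 ratio of 1.49 (1.32 to 1.69, 100th percentile of random lists). Cdkn1a, which encodes the cell cycle inhibitor p21 (ENSMUSG00000023067, chromosome 17, 29090976 to 29100727), stood at 4.49 CPM in CTRL and 204 CPM in CKO, 45.0-fold higher (log2 5.49, 5.08 to 5.96). Eda2r, an X-linked receptor gene, stood at 0.780 and 53.2 CPM, 64.2-fold higher. Bax, a pore former of apoptosis, stood at 170 and 391 CPM, and Rps27l at 370 and 669 CPM. Sesn1 and Btg2 were the members between, with log2 ratios of -0.07 and 0.11. In mesenchymal-like cells the median of the same list was 0.05 (-0.04 to 0.08, 83.3rd percentile), with 1 of 17 measured genes over 1.5-fold higher.

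**Figure D2:**
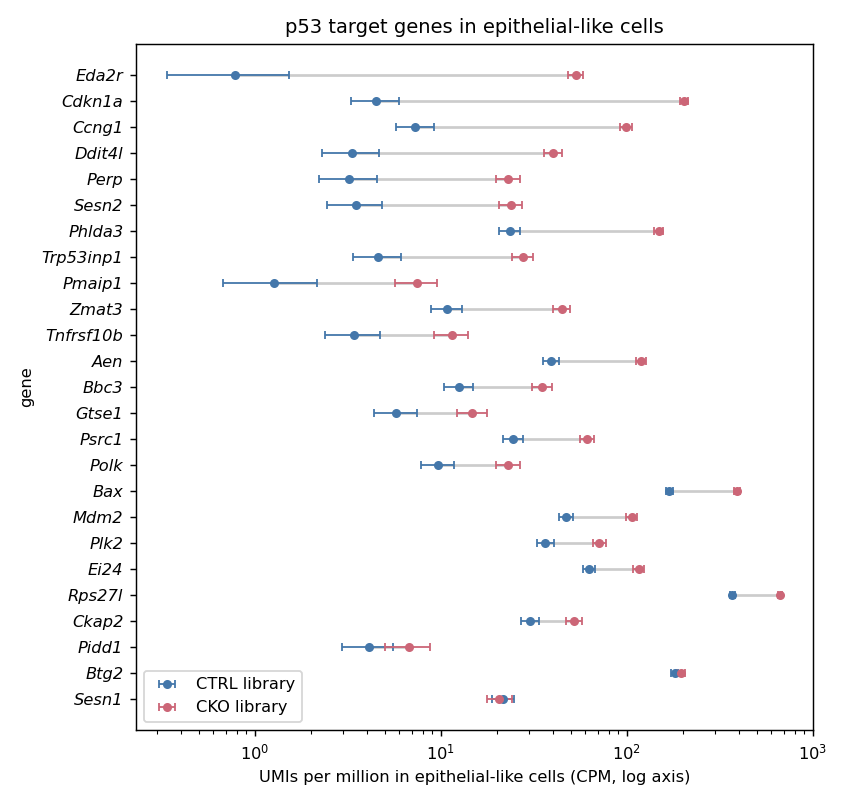
CPM (log axis) of the 25 measured p53 target genes in epithelial-like cells of the CTRL and CKO libraries, with exact 95% Poisson intervals as error bars. Cdkn1a stands at 4.49 CPM in CTRL and 204 CPM in CKO, and Sesn1 has a log2 ratio of -0.07.

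Among 7298 genes that passed the filter in epithelial-like cells, 195 were 2-fold or more higher in CKO and 177 were 2-fold or more lower. This is a description of these libraries and not a count of altered genes. Among them were Xist, Tsix and 4 Y-linked genes, and without these the counts were 193 and 173. The lower genes also held 6 haemoglobin genes, and without both sets 167 were left. A minimum of 50 CPM gave 72 higher and 80 lower genes, and thinned cells gave 91 higher. Vgll2, a cofactor of TEAD transcription factors, had 0 UMIs in CTRL and 187 in CKO, at least 79.6-fold higher against a floor of 3 counts over the class. Ano3, of the anoctamin family, had 0 and 175 UMIs, 74.5-fold higher against the same floor (lower limit of the log2 ratio 5.91). Dscaml1, a cell adhesion gene, had 1 and 265 UMIs (log2 ratio 7.82, 5.91 to 13.71). Trp53cor1, a long noncoding RNA next to Cdkn1a, had 1 and 221 UMIs (7.56, 5.65 to 13.45), and Slc30a10, a manganese exporter, had 2 and 167 UMIs (6.42, 4.86 to 9.79). Besides Eda2r and Cdkn1a, the other genes named by rank were Lor (47.8-fold), Fam171b (35.9-fold, from 2.15 to 78.8 CPM), Atp8b5 (29.7-fold), Krt20 (28.5-fold) and Thsd7a (27.8-fold).

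Cftr, the chloride channel of airway epithelium, headed the genes lower in CKO epithelial-like cells, at 92.6 CPM in CTRL and 3.36 CPM in CKO, 27.0-fold lower (log2 -4.76, -5.39 to -4.23). Bak1, a pore former of apoptosis, stood at 21.8 and 0.872 CPM, 23.3-fold lower. Krtcap2, a subunit of the oligosaccharyltransferase, stood at 202 and 15.9 CPM, 12.6-fold lower. The others named by rank were Sh3rf3 (24.0-fold lower), Adprhl2 (18.1-fold), Serpinb6b (38.9 to 2.37 CPM), R3hcc1 (15.1-fold), Ttc5 (14.3-fold), Tex261 (14.3-fold), Cpe (11.3-fold), Shcbp1 (11.3-fold) and Slc35f1 (10.7-fold). The 5 of these genes that differed most from the mesenchyme had near-equal levels there in both libraries, with an epithelial minus mesenchymal log2 ratio of -4.59 for Bak1, -4.18 for Adprhl2, -3.89 for Tex261, -3.85 for R3hcc1 and -3.84 for Ttc5. It was -3.76 for Snhg17, which was 1.82-fold higher in CKO mesenchyme. In the other direction it was 3.82 for Chn2, 2.98 for Enox1, 2.86 for Cox6b2, 2.61 for Phlda3, 2.45 for Crabp1 and 2.29 for Kif26b, among 6074 genes that passed in both classes and were open to naming.

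**Figure D3:**
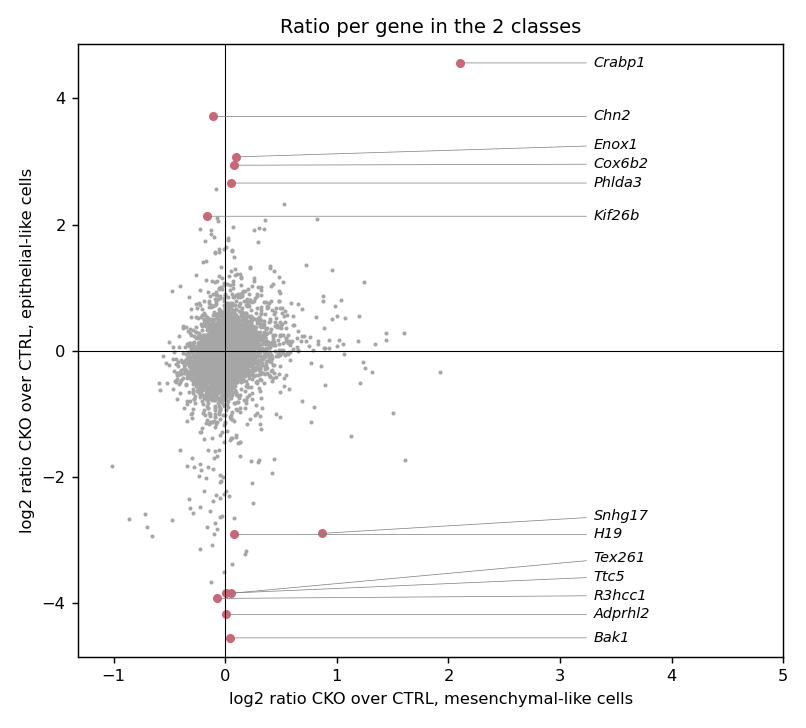
Log2 ratio of CKO over CTRL per gene in mesenchymal-like cells (horizontal axis) and epithelial-like cells (vertical axis) for 6304 genes, with named genes in red; Xist, Tsix and the Y-linked genes are left out. Bak1 and Adprhl2 lie near 0 on the horizontal axis and below -4 on the vertical axis.

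Genes of the distal tip, the progenitor zone that drives branching, went both ways. Of 17 measured members, 4 were over 1.5-fold higher, 6 lower and 7 between (median log2 ratio -0.05, -0.15 to 0.09, 36.8th percentile). Clu (-3.07), Sftpc, the surfactant protein C gene (251 to 74.5 CPM, -1.75), Wnt7b (157 to 53.9 CPM, -1.54), Shh (59.3 to 26.4 CPM, -1.17) and the FGF-responsive factor Etv5 (233 to 115 CPM, -1.02) were lower, whereas Id2 was higher (346 to 541 CPM, 0.65). The log2 ratio was 0.13 for Sox9 and -0.15 for Foxp2. Of 8 measured proximal airway genes, 2 were higher, 2 lower and 4 between (median 0.13, 89.1st percentile). Perp, which is also a p53 target, had a log2 ratio of 2.83, Cldn4 one of 1.32, Krt15 one of -2.61 and the airway factor Sox2 one of -0.94 (80.3 to 41.8 CPM). Wfdc2 and Cd24a, the most abundant members, had ratios of -0.03 and -0.25. The distal median turned to 0.27 in cells thinned to 5000 UMIs, and the proximal median to -0.02 with mitochondrial, ribosomal protein and haemoglobin genes out of the total. The latter came with a different set of members at 5 CPM or more, since that total moves every ratio equally.

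Among signalling lists in epithelial-like cells, 6 of 11 FGF response genes were over 1.5-fold higher, 1 lower and 4 between (median log2 ratio 0.75, 100th percentile). Dusp4, at 3.41 and 9.96 CPM, and Il17rd, at 3.22 and 7.22 CPM, had log2 ratios of 1.53 and 1.16, Etv5 was the lower member, and Ccnd1 had a ratio of -0.18. Of 9 WNT response genes, 4 were higher, 1 lower and 4 between (median 0.38, 99.9th percentile), with Sp5 at 1.10, Tnfrsf19 at -1.06 and Znrf3 at -0.10. Of 6 hedgehog response genes, 1 was higher and 2 lower (median -0.33, 7.42th percentile), including Hhip at -2.95. Hhip stood at 13.0 CPM in CTRL epithelial-like cells and 581 CPM in CTRL smooth muscle-like cells. RNA from other cells was not separated from its epithelial level. The BMP and TGF-beta list had a median of 0.11 (90.9th percentile) and 3 measured Notch genes one of 0.12 (81.7th percentile). S phase genes had a median of -0.32 (-0.36 to -0.28, 0th percentile), with 0 of 36 over 1.5-fold higher and 4 lower, including Rrm2 at -1.02. G2 and M phase genes had a median of -0.09 (-0.12 to -0.05, 3.29th percentile), which turned to 0.02 when each cell had equal weight.

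Extracellular matrix genes were higher as a group in CKO epithelial-like cells, with 8 of 18 over 1.5-fold higher and 1 lower (median log2 ratio 0.50, 100th percentile); Eln had a ratio of 2.23, Fbln5 one of 1.67 and Sparc one of 0.40. Eln and Fbln5 were also leading genes of clusters found almost only in CKO, as was Crabp1, a mesenchymal gene that stood at 0.878 CPM in CTRL epithelial-like cells and 21.8 CPM in CKO ones, so RNA from those cells was not separated from the epithelial level. Hypoxia and glycolysis genes had a median of -0.33 (0.01th percentile), with Bnip3 at -1.48 and Slc2a3 at 1.60. The integrated stress list had a median of 0.24 (99.8th percentile), with 2 of 13 over 1.5-fold higher and 0 lower. It was headed by Sesn2 at 2.74, which is also on the p53 target list. Of 27 imprinted genes, 3 were higher, 5 lower and 19 between (median -0.05, 27.2th percentile). H19, whose imprinting control region holds CTCF sites, stood at 496 CPM in CTRL and 66.0 CPM in CKO (-2.91), whereas its neighbour Igf2 had a ratio of 0.15, or -0.03 without the epithelial-like cluster of low UMI counts. Phlda2 and Cdkn1c, imprinted neighbours on chromosome 7, had ratios of 1.71 and -1.44. Medians were -0.07 for epithelial junction genes (30.2th percentile), -0.13 for lung transcription factors (2.83th), -0.64 for 5 Hox genes (2.24th), -0.01 for dissociation stress genes (55.0th) and 0.04 for smooth muscle contractile genes (71.3rd). Haemoglobin genes, which epithelial cells do not express, had a median of -2.67, with Hbb-y at 1262 CPM in CTRL and 198 CPM in CKO.

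**Figure D4:**
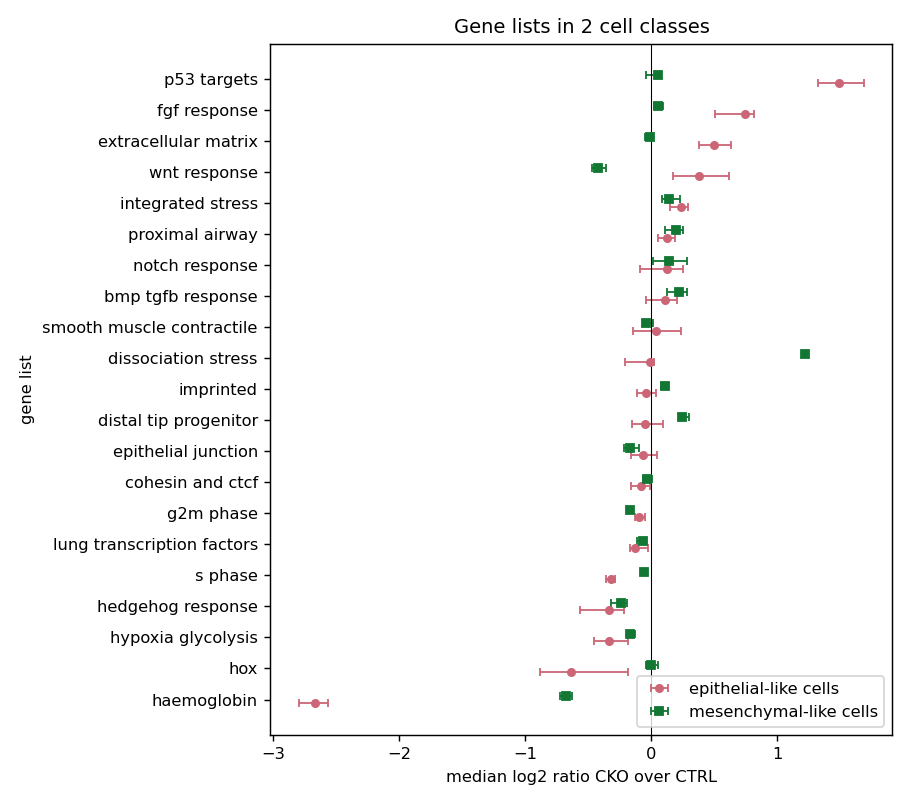
Median log2 ratio of CKO over CTRL (horizontal axis) of each gene list in epithelial-like and mesenchymal-like cells, with 95% counting intervals of the median as error bars. The p53 targets stand at 1.49 in epithelial-like and 0.05 in mesenchymal-like cells, and the dissociation stress genes at -0.01 and 1.22.

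Per cell, Cdkn1a UMIs were found in a large part of the CKO epithelial-like cells and in few control cells. With each cell thinned to 5000 UMIs, 5 of 385 CTRL cells (0.423 to 3.00%) and 48.9% of 272 CKO cells (42.8 to 55.0) had a Cdkn1a UMI; 136 and 138 shallower cells were left out, and the median depths before thinning were 9489 and 8567.5 UMIs. The unthinned shares were 4.22% and 56.8%, and the thinned share in mesenchymal-like cells, at median depths of 16907 and 15374.5 UMIs, was 1.76% in CTRL and 1.24% in CKO. Finer clustering gave separate distal sub-clusters for each library, one of 205 CTRL cells and 1 CKO cell, with Sox9 at 240 CPM, Etv5 at 327 CPM and Sftpc at 367 CPM in CTRL. The other, of 159 CKO cells and 1 CTRL cell and with Cdkn1a among its leading genes, had Sox9 at 243 CPM, Etv5 at 155 CPM, Sftpc at 103 CPM and Cdkn1a at 253 CPM in CKO. In a shared sub-cluster of shallow cells (128 and 126), Sox9 stood at 65.9 CPM in CTRL and 175 CPM in CKO, Etv5 at 56.5 and 70.4 CPM, Sftpc at 135 and 86.6 CPM, and Cdkn1a at 1.05 and 198 CPM. A Sox2-rich sub-cluster shared by both libraries (187 and 124 cells) had Sox2 at 242 CPM in CTRL and 133 CPM in CKO, and Cdkn1a at 4.10 and 87.2 CPM.

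Mesenchymal-like cells differed less in size of ratio than epithelial-like cells, with 32 of 7060 genes 2-fold or more higher and 5 lower. Without Xist, Tsix and the 4 Y-linked genes these counts were 30 and 1. With all genes, 20 draws of as many mesenchymal as epithelial cells gave medians of 39.5 higher (26 to 66) and 6 lower (4 to 13). Genes that respond to tissue dissociation stood higher in CKO, with 17 of 20 over 1.5-fold higher and 0 lower (median log2 ratio 1.22, 1.19 to 1.25, 100th percentile). The heat shock gene Hspa1a was 18.8-fold higher (1.64 to 31.1 CPM), Atf3 3.79-fold, Jun 3.03-fold (203 to 615 CPM), Nr4a1 2.83-fold and Junb 2.72-fold higher. Cdh18 (5.51-fold), Crabp1 (4.31-fold) and Adamts18 (3.05-fold) were also higher; Crabp1 and Adamts18 headed the markers of the largest cluster found almost only in CKO. Samd1 was 2.02-fold lower, Rbm46 1.80-fold, Gata4 1.77-fold, Sgip1 1.66-fold, Myocd 1.60-fold, Hist1h1b 1.51-fold and Synpo2 1.51-fold lower. Myh11, a marker used to name smooth muscle, was also lower (log2 ratio -0.59). The ratios of Synpo2 and Myh11 turned to 0.34 and 0.11 on the log2 scale when each library was clustered on its own.

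WNT response genes in mesenchymal-like cells had a median log2 ratio of -0.42 (-0.47 to -0.36, 0th percentile), with 1 of 8 over 1.5-fold lower and 0 higher, Sp5 at -1.13 and Lef1 at -0.48. Hedgehog response genes had a median of -0.24 (0.01th percentile), with 1 of 10 over 1.5-fold lower and 0 higher, and the receptor gene Ptch1 stood at 180 CPM in CTRL and 125 CPM in CKO (-0.52). The class mixed 10 clusters in different shares per library, and Ptch1 was a leading gene of 2 that held more CTRL cells. Inside the clusters the WNT median ran from -0.56 to 0.12 (median -0.28) and the hedgehog median from -0.36 to 0.22 (median -0.11), each below 0 in 9 of 10. The BMP and TGF-beta list had a median of 0.22 (99.99th percentile), with Ccn2 at 1.37 and Id3 at 0.49. G2 and M phase genes had a median of -0.17 (0th percentile), with Mki67 at -0.50. The compared endothelial cluster, with 264 CTRL and 280 CKO cells, had 158 of 6798 genes 2-fold or more higher and 8 lower, among the latter 3 Y-linked genes. Xist and 7 haemoglobin genes were among the higher ones, and without them 150 were left. Agr2 (47.5-fold), Hspa1a (40.3-fold), Fbln2 (21.8-fold) and Pdlim3 (16.7-fold) were among the genes higher there. Samd1 (2.34-fold), Ankrd37 (2.30-fold), Depp1 (2.09-fold), Snhg4 (2.09-fold) and Itga4 (2.02-fold) were lower. Dissociation stress genes had a median of 1.18 in that cluster and haemoglobin genes one of 1.74, both at the 100th percentile. Smooth muscle-like cells had 473 of 7636 genes 2-fold or more higher and 489 lower, more than epithelial-like cells. That class joined a cluster of 269 CTRL and 138 CKO cells with one of 24 and 367, so its counts compare different mixtures.

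Within the CTRL library, 15 of 37 signalling genes stood 2-fold or more above the next of 8 compared classes, whereas for 9, among them Nrp1 and Igf2, the intervals of the first 2 classes overlapped. The genes below were picked among signalling genes and lung transcription factors whose first 2 intervals were apart, and none of them was higher in cardiomyocyte-like, erythroid-like or megakaryocyte-like cells. Fgf9, a growth factor of the lung surface, stood at 195 CPM in mesothelial-like cells (186 to 204) and 2.73 CPM in epithelial-like cells, the next class. Fgf10, which draws out epithelial buds, stood at 32.7 CPM in mesenchymal-like cells, and Wnt2 at 178 CPM there. Shh stood at 59.3 CPM and Wnt7b at 157 CPM in epithelial-like cells, against 3.05 and 2.69 CPM in the next class. The hedgehog targets Hhip and Ptch1 were highest in smooth muscle-like cells, at 581 and 255 CPM, as were Igf1 (849 CPM) and Foxf1 (392 CPM). Pdgfa was highest in mesothelial-like cells at 150.3 CPM. Foxp2 (2358 CPM) and Etv5 (233 CPM) were highest in epithelial-like cells, and Hoxb5 in mesenchymal-like cells (170 CPM).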

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

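All tests in this part except that in Nkx2-1-positive cells, namely those of a library-wide shift, dissociation stress, neighbouring tissue, lung identity, a mixed pool and Xist in male cells, were chosen only after the results were seen.

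The higher p53 target genes in CKO epithelial-like cells stood out in the comparison itself. A shift of the whole CKO library is argued against by the same list in mesenchymal-like cells, whose median log2 ratio was 0.0523. In the other compared classes the median ran from -0.03 in smooth muscle-like to 0.27 in myeloid immune-like cells. In the latter it lay at the 99.5th percentile, with 5 of 19 genes over 1.5-fold higher and 2 lower. Dissociation stress is argued against because the dissociation stress genes had a median of -0.00963 in the epithelial-like cells, although it was 1.22 in the mesenchyme. Epithelium of another organ is argued against by cells with an Nkx2-1 UMI, in which Cdkn1a was 43.0-fold higher in CKO (32.4 to 59.6, 362 CTRL and 271 CKO cells). A p53 response in CKO lung epithelium is therefore a hypothesis consistent with these values; the mesenchymal median also argues against an effect of sex common to all cells, whereas one of sex in the epithelium alone, of Cre itself or of a single embryo was not tested and stays open.

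Of the cell classes outside the comparisons, erythroid-like and unnamed cells took smaller shares in CKO (1.23% against 2.58%, 0.581% against 1.25%) and others larger ones: other mesenchymal-like cells 19.8% against 0.0144%, skeletal muscle-like cells 1.49% against 0 of 6943 cells, and cardiomyocyte-like cells 2.96% against 1.28%. Tissue next to the lung in the CKO suspension is a candidate explanation: the share of cardiomyocyte-like cells, a class both libraries held, was 2.96% in CKO (2.61 to 3.35) and above the CTRL interval (1.03 to 1.58), and the order held but the shares fell to 0.0864% (CTRL, up to 0.188) and 0.391% (CKO, from 0.269) at Leiden resolution 0.5, 6 and 33 cells, and to 0.0856% and 0.667% with no cell filter, 7 and 66 cells. A loss of lung identity in CKO mesenchyme stays open, since Hoxa5 plus Hoxb5, genes not used for naming, stood at 59.3% of the level in the shared mesenchyme (57.1 to 61.5), between the bounds set for and against it. Earlier tests of both explanations by Tbx4 plus Tbx5 had counted for extra tissue and against a loss of lung identity, and were set aside as circular because these genes had split the classes. The cardiomyocyte share does not bear on the mesenchymal clusters directly, so for these extra tissue and a loss of lung identity cannot be told apart with 1 library per group.

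Xist at 592 CPM in CKO, labelled male, stood above its CTRL level of 0.630 CPM. A pool of male and female embryos is argued against, since the 4 Y-linked genes fixed beforehand stood at 0.964% of their CTRL level. Xist switched on in male cells is argued against as well, since 3.58% of CKO cells (302 of 8440) had a UMI of these genes, against 85.5% of CTRL cells, while 93.5% had an Xist UMI. A first version of the pool test summed all 725 genes annotated on Y and gave 61.4%, which would have fitted a pool; it was replaced after 51718 of its 52056 CKO UMIs proved to come from Gm47283, which had 45292 UMIs in CTRL. The CKO cells thus carried the transcripts of female cells. Whether they came from a female CKO embryo under a male label or from an exchange with a sample outside the series stays open.

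WNT response genes had medians of opposite sign, 0.38 in epithelial-like and -0.42 in mesenchymal-like cells, and the difference was not tested; the limits by which it was picked were set after the data were seen.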

How the results depend on the processing

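The alternatives without the low-UMI epithelial-like cluster, with Nkx2-1-positive cells and with Tbx5-positive cells were chosen after the data were seen. No paired analysis was possible because each group had 1 library. Of the alternative values for main results, 113 stayed within their counting interval or 1.5 times the count, 31 moved out of it and 2 changed sign from an interval apart from 0; for other single genes and lists these were 885, 198 and 7. The distal tip median, whose interval held 0, also changed sign in thinned cells, with no cell filter, at Leiden resolution 0.5 and with the stricter gene filter. The p53 target median in epithelial-like cells lay between 1.42 and 1.56 in every alternative. The stricter cell filter gave epithelial shares of 5.72% in CTRL and 3.66% in CKO and mesenchymal shares of 72.5% and 49.4%. No cell filter gave 8.35% epithelial cells in CTRL, 62.3% and 44.5% mesenchymal cells, and a proximal airway median of 0.19. Mesenchymal shares were 66.0% and 45.4% with doublets kept, 63.8% and 44.3% at Leiden resolution 2, and 65.5% and 46.0% with libraries clustered on their own, which also gave log2 ratios of 0.34 for Synpo2 and 0.11 for Myh11. Leiden resolution 0.5 gave 8.67% epithelial cells in CTRL and 49.3% mesenchymal cells in CKO. Equal weight per cell gave a G2 and M phase median of 0.0184 and a Ctcf log2 ratio of -0.25. Thinned cells gave 91 higher epithelial genes, a Ctcf ratio of -0.52, and medians of 0.0208 for cohesin and CTCF, 0.27 for distal tip and 0.26 for proximal airway genes. Their smaller UMI total also raised the CPM that the minimum of 100 UMIs asks for. The counts of genes followed the gene filter by construction: the stricter one gave 72 higher and 80 lower epithelial genes and 20 and 2 mesenchymal genes, and no CPM filter, with the minimum also lowered from 100 to 10 UMIs, gave 1159 genes 2-fold or more higher in CKO epithelial-like cells, 865 lower there, and 970 and 266 in mesenchymal-like cells. These filters gave proximal airway medians of 0.28 and 0.0137, mesenchymal FGF response medians of -0.0622 and -0.0307, and, with no CPM filter, a mesenchymal epithelial junction median of 0.11. The total without mitochondrial, ribosomal protein and haemoglobin genes gave a proximal airway median of -0.0158, and leaving out the low-UMI cluster gave Igf2 a ratio of -0.0337. For all of these but the counts under other gene filters and the last proximal airway median the cause was not tested. The distal tip median thus had no stable sign. The proximal airway median changed sign in 1 alternative, the total without mitochondrial, ribosomal protein and haemoglobin genes. The median of all genes in epithelial-like cells moved only from -0.0339 to -0.0245 there. Leaving genes out of the total moves every log2 ratio by the same amount. The change of sign thus came from which members reached 5 CPM, not from their ratios.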

Other observations

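The test of nearby higher genes was set before its result was seen; the tests of a response in part of the cells and of neighbours without haemoglobin genes, and the choice of the mesothelial genes, came after.

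Mesothelial-like cells, which cover the lung surface, were 1 cluster with 339 CTRL and 320 CKO cells, and 221 of 7396 genes were 2-fold or more higher in CKO and 55 lower, or 220 and 51 without Xist and the 4 Y-linked genes. Without 6 haemoglobin genes as well, 214 were higher. Leiden resolution 2 split these cells into a cluster of 313 CTRL and 119 CKO cells, with Tbx4 plus Tbx5 at 154 CPM, and one of 14 and 199 cells at 52.2 CPM with Tbx18 and Myl7 among its leading genes, and so did the stricter cell filter (268 and 97, 13 and 172 cells) and doublets kept (341 and 132, 13 and 205 cells). The ratios below therefore compare different mixtures of these clusters, and a change within either was not separated from the mixture. The highest ratios, named by the rule used for the other classes but added after the values were seen, included Hand2, a transcription factor of heart and limb development, with 2 and 196 UMIs (log2 ratio 6.41, 4.86 to 9.79). Its neighbour Hand2os1 had 3 and 203 UMIs (5.98, 4.63 to 8.49), and Ppp1r14c (65.2-fold), Ctnna3 (32.9-fold) and Apela (32.4-fold) were also higher. Col19a1 (5.26-fold), Grin3a (5.04-fold), Gpc5 (4.18-fold), Hhip (160 to 39.3 CPM) and Sgcz (3.69-fold) were lower. Of 9 hedgehog response genes, 6 were over 1.5-fold lower and 1 higher (median log2 ratio -1.27, 0th percentile). G2 and M phase genes had a median of -0.38 (0th percentile). Dissociation stress genes had a median of 1.25 and haemoglobin genes one of 2.07, both at the 100th percentile.

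A response in only some CKO epithelial-like cells, as after a mosaic deletion, was tested in cells of 5000 UMIs or more and stays open. The test first took 6 of the lowest genes, then all 173 genes over 2-fold lower (40.3% of the CTRL level in the 73 CKO cells without a Cdkn1a UMI, 30.3% in the 199 with one), among them haemoglobin genes, which epithelial cells do not express. It was replaced by the 50 of these genes with their highest CTRL level in epithelial-like cells. They stood at 44.1% (42.1 to 46.1) in the Cdkn1a-negative cells and 36.9% in the positive ones. All had been picked as lower in CKO epithelial-like cells as a whole, the Cdkn1a-negative ones included. A level below CTRL in the negative cells was thus partly set by the choice of genes. The other 25 p53 genes of the list, summed, stood at 1091 CPM in CTRL, 1481 CPM in the Cdkn1a-negative and 2501 CPM in the Cdkn1a-positive CKO cells, so by these genes the negative cells lay nearer to CTRL; they were also shallower (median 8932 against 20478 UMIs) and had more Sox2 (93.4 against 36.2 CPM). The sum of lower genes thus cannot decide the question, and depth and position along the airway were not separated from the response.

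Loss of a CTCF boundary could let a gene lose activity to a higher neighbour. Of 173 lower genes with a position, 6 (3.47%) had a gene 2-fold or more higher within 200 kb. The mean in 10000 random draws was 4.11%, which put the lower genes at the 35.3rd percentile. They thus had no excess of such neighbours. Gains under 2-fold, genes under the 20 CPM filter and distances over 200 kb were not counted, so the test does not exclude such a loss. The 6 included H19 at 190105 bp from Ctsd, with the lower gene Mrpl23 between them, and Cdkn1c at 42100 bp from Phlda2. Of the lower genes, 14 (8.09%) lay near another lower gene, against 4.51% by chance (98.2nd percentile), but 6 of these were haemoglobin genes, and without haemoglobin genes it was 8 of 167 (4.79%) against 4.39% (61.6th percentile). Higher genes near higher genes were 18 of 192 (9.38%) against 4.26% (99.9th percentile). In such same-direction counts each gene of a neighbouring pair counts for the other, which genes drawn at random need not do, so these percentiles may be overstated. Trp53cor1 and Cdkn1a, both higher, lie within 200 kb of each other, and no such pair was left out. Whether higher genes lie together more than by chance was therefore not decided.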
